A study of Mus musculus with 2 samples.

How the data were processed

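H3K4me1 ChIP-seq was measured in hindbrain of mouse embryos at embryonic day 10.5 in 2 biological replicates, pools of 69 and 51 embryos of both sexes. Per the labels, the assembly is mm10 and a possible input control is named. The replicate numbers come from the labels.

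The authors deposited 4 peak lists in narrowPeak format: a list called on each replicate, a list called on both replicates pooled, and a list of replicated peaks. Every peak of the replicated list is a peak of the pooled list, which was tested on the lists. Each peak has a position, a fold enrichment (signal value), a −log10 p-value and a −log10 q-value as deposited by the authors, and a summit position that was not used. The fold enrichment is read from the narrowPeak format, since the deposited notes do not name its scale. The smallest deposited −log10 p-value was 2.02, so no peak had a p-value above 0.01 and the lists hold many weak peaks. The aligner, the peak caller, their versions, the duplicate filter and the rule that makes a peak replicated are not stated in the labels or in the notes deposited with the samples. The lists are not scaled to each other: a deeper library gives more and wider peaks at the same limit, so covered length and peak number depend on depth, which the lists do not give. No interval that needs read counts is given for this reason.

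Peaks on the 19 autosomes and chromosome X were used. Left out were 1 peak of replicate 1, 3 of replicate 2, 4 of the pooled list and 1 of the replicated list, on chromosome Y or on scaffolds. The reference was GRCm38.p6 with the GENCODE M21 annotation, which has the coordinates of mm10. Over the 4 lists 23 peaks touched an assembly gap of at least 100 bp. Each of 21646 protein-coding genes was given the TSS of its principal transcript, and all basic protein-coding transcripts were used for the distance of a peak to a TSS. Exon, intron and intergenic classes refer to protein-coding genes and to the midpoint of a peak. A TSS was called CpG-rich when the observed over expected CpG ratio was at least 0.6 and the GC content at least 50% within 500 bp.

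Computation was in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Overlap of lists means at least 1 bp. Circular shifts moved each chromosome's peaks by a random offset of at least 1 Mb with assembly gaps taken out, 1000 times for the overlap and promoter share of the replicates, 100 times for the other classes, lists and alternatives and 20 times for motifs, and the permutation p is one-sided. For correlations, peaks were matched by the largest overlap in both directions. Coverage of a gene is the percent of bases within 25 kb of its TSS in peaks. The percentile of a list is that of its median among 10000 random lists of the same size and the same GC deciles, and a list was called above or below when it lay outside the central 95% (percentiles 2.5 and 97.5). For motifs, windows of 1 kb on peak midpoints over 2.5 kb from a TSS were compared with up to 200000 windows outside every peak, in GC bins of 2%. In the replicated list 134723 windows were used, and 316 had no GC match. The random seed was 20. On simulated lists of 15 genes drawn at random from all genes, 3 of 100 unchanged lists were called. Of 100 such lists with doubled coverage plus 5 percentage points, 94 were called above. A planted overlap and a planted correlation were also recovered, and shifted peaks gave a median motif ratio close to 1.

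With 1 group there was no test between groups. Values per replicate are given with the mean and SD of 2 replicates, and with 2 replicates no exact test can reach 0.05. The measurements, the 21 gene lists, the 13 motifs and the alternatives were fixed before the data were examined. The lists were: Hox groups 1 to 5, Hox groups 9 to 13, rhombomere, midbrain-hindbrain boundary, dorsoventral progenitor, neural progenitor, early neuron and signalling genes (joined as the hindbrain lists, although Hox groups 9 to 13 act in trunk and limbs), then forebrain, neural crest and mesenchyme, endothelial, erythroid, macrophage, cardiac, skeletal muscle, liver, postnatal neural, pluripotency, housekeeping, olfactory receptor and vomeronasal receptor genes. The central 95% limit was set once the peak lists were in hand and before any coverage was computed. The genes named were the 2 highest and the lowest member of each hindbrain list, the highest and lowest member of every other list, 16 genes fixed in advance (Egr2, Mafb, Hoxa2, Hoxb1, Gbx2, En2, Phox2b, Atoh1, Sox2, Foxg1, Six3, Alb, Myh6, Hbb-bh1, Sox10 and Kdr), and the genes at the 10 longest domains. The alternatives were a q-value limit of 1e-05, each replicate left out, other windows (10 and 100 kb for genes, 2.5 kb for promoters, 400 bp for motifs), other overlap rules, the other peak lists, unmatched random lists, joining of peaks within 1 or 3 kb, and scaffolds kept. Added after the data were seen were the leaving out of X-linked genes, lists matched also on CpG-rich promoters, windows without the 2.5 kb around the TSS, the single Hox clusters, the hindbrain minus other tissue difference without CpG-rich TSSs and less the median of genes of the same GC decile and promoter class, and chromosome X at CpG-rich TSSs.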

Results

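Hindbrain was dissected from mouse embryos (strain B6NCrl) at embryonic day 10.5, the stage at which the hindbrain is divided into rhombomeres and its first neurons are born. Chromatin was immunoprecipitated with an antibody against H3K4me1 (monomethylation of lysine 4 of histone H3, a mark of enhancers and of the flanks of promoters) and sequenced. The samples formed 1 group of 2 biological replicates, each a pool of hindbrains of both sexes, from 69 embryos in replicate 1 and 51 embryos in replicate 2. There was no second tissue, stage or treatment, so the measurements concern where the mark lay in this tissue and how far both pools gave the same picture. Sequencing depth was not given in the peak lists and is unknown. All positions are on mm10.

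The mark covered a similar small part of the genome in both pools. Peaks covered 147 Mb (5.75% of the sequence) in replicate 1 and 164 Mb (6.42%) in replicate 2, a mean of 156 ± 12.04 Mb (SD, n = 2). Replicate 1 had 240660 peaks with a median width of 367 bp, and replicate 2 had 206700 peaks with a median width of 477 bp. Fewer and wider peaks in replicate 2 thus covered more sequence. The median fold enrichment of a peak was 2.88 in each replicate. The authors' pooled list held 279014 peaks over 181 Mb, and their replicated list held 165111 of these peaks over 155 Mb. With a q-value under 1e-05, 37.2% of the peaks of replicate 1 and 50.4% of those of replicate 2 remained.

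Most peaks were found in both pools, and the strong ones nearly always. Of the peaks of replicate 1, 74.2% overlapped a peak of replicate 2, and 73.9% of the peaks of replicate 2 overlapped a peak of replicate 1. After circular shifts of the lists along the chromosomes the mean share was 11.2%, and none of 1000 shifts exceeded 12.2% (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). Among the weakest 10% of peaks by p-value the overlap was 46.1% in replicate 1 and 42.7% in replicate 2, and among the strongest 10% it was 100% in both after rounding. Fold enrichments of 142904 matched peak pairs were correlated across peaks, with a Spearman's rho of 0.710 and a Pearson's r of 0.772 on the log2 scale. Peaks are not independent replicates, so no p-value is attached to these correlations. The authors kept 59.2% of their pooled peaks as replicated, and 94.6% of those with a q-value under 1e-05. The peaks they kept had a median fold enrichment of 3.16 and a median width of 627 bp, against 2.25 and 207 bp for those they left out. Of the 165111 replicated peaks, 16302 did not overlap peaks of both replicate lists. The term replicated thus follows the authors' list and does not mean found in both lists for every peak.

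Peaks lay mainly in introns and between genes, and were over-represented at promoters. Introns of protein-coding genes held 47.8% ± 1.29 of peak midpoints (SD, n = 2), and 37.5% ± 0.943 lay outside protein-coding genes. Within 1 kb of an annotated protein-coding transcription start site (TSS) lay 9.32% ± 0.289 of midpoints, and exons held 5.44% ± 0.0560. Compared with shifted lists, promoters were over-represented 4.24 ± 0.137 times, exons 1.61 ± 0.0103 times and introns 1.303 ± 0.0366 times, whereas intergenic sequence held 0.649 ± 0.0170 of its shifted share. None of 1000 shifts reached the promoter share of either replicate (one-sided permutation p = 0.000999, the smallest possible).

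Around the TSS, the mark formed a pair of flanking maxima with a dip between them at CpG-rich promoters, and a plain maximum at other promoters. At the 10035 CpG-rich TSSs, coverage by replicated peaks reached 57.4% between 600 and 500 bp upstream, fell to 34.1% over the 100 bp downstream of the TSS, and reached 76.0% between 1000 and 1100 bp downstream. At the other 11611 TSSs it was highest close to the TSS, at 29.6% between 100 and 200 bp downstream. The ratio of flank coverage (1 to 2 kb from the TSS) to centre coverage (within 200 bp) was 1.32 ± 0.297 at CpG-rich TSSs and 0.480 ± 0.0173 at the others (SD, n = 2). Over all 21646 protein-coding TSSs the ratio was 0.906 ± 0.125. The dip was shallower in replicate 2: the centres of CpG-rich TSSs were covered to 28.2% in replicate 1 and 42.5% in replicate 2, while their flanks were covered to 43.2% and 47.2%. A replicated peak lay within 1 kb of the TSS of 67.4% of genes.

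**Figure D1:**
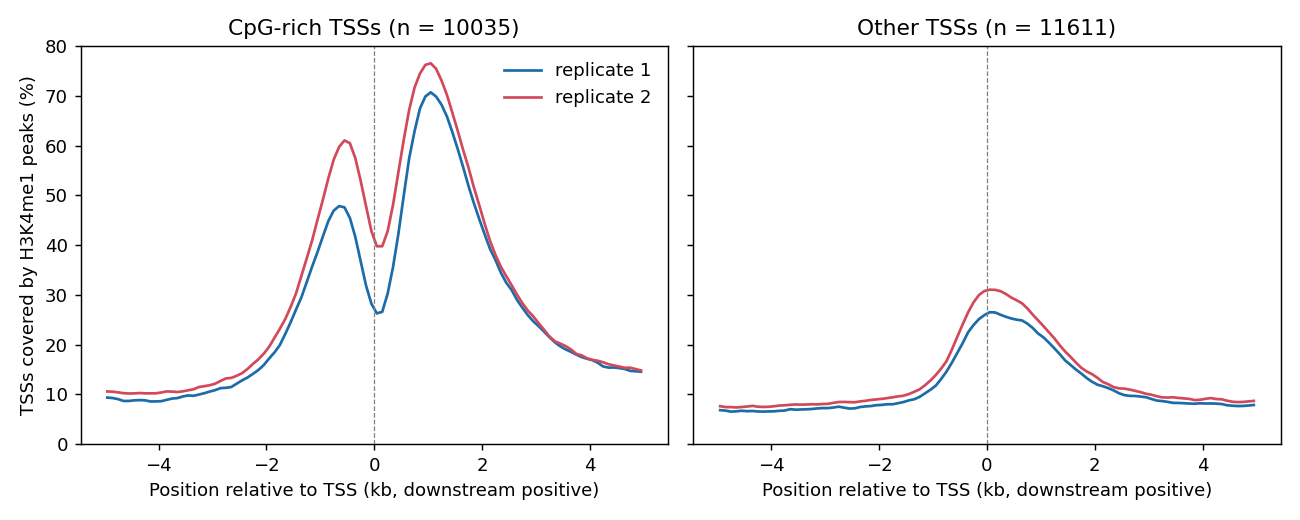
Share of TSSs covered by H3K4me1 peaks (y axis, percent) in 100 bp steps from 5 kb upstream to 5 kb downstream (x axis, kb), for 10035 CpG-rich TSSs on the left and 11611 other TSSs on the right. Each line is a replicate; CpG-rich TSSs show a dip at the TSS, with centre coverage of 28.2% in replicate 1 and 42.5% in replicate 2, and the other TSSs show no dip.

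To ask which genes carried the mark, coverage was taken as the percent of the 25 kb on either side of the TSS that lay in replicated peaks. Its median over all genes was 7.29%, and 19.0% of genes had none. Each list of genes was set against random lists of the same size and GC content. Of 21 lists, 9 had a median above the central 95% of random lists, 3 had a median below it, and 9 lay within it. For lists of scattered genes, about 1 in 20 lies outside by chance alone. Neighbouring genes share windows, as in the Hox lists and for any clustered members of other lists. The percentiles of such lists are not calibrated, and this rate does not hold for them. These percentiles describe these libraries and are not tests between conditions.

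The neural progenitor, midbrain-hindbrain boundary and rhombomere lists had the highest medians of the 21 lists. Over 18 general neural progenitor genes the median coverage was 39.2% against 12.2% in random lists (percentile 100), and every member was above the median of all genes. Notch1, the receptor through which progenitors are kept from differentiating, was covered to 76.3% (75.5% ± 2.299 over the replicates, SD, n = 2). Nes, which encodes the intermediate filament nestin, was covered to 68.5% (68.1% ± 1.68), and Sox2, a transcription factor of neural progenitors, to 59.3% (56.5% ± 6.62). The lowest member was the X-linked Sox3 at 8.44%. Over 15 rhombomere genes the median was 31.4% against 12.1% (percentile 100). Epha4, an ephrin receptor of alternating rhombomeres, was highest at 61.2% (59.5% ± 3.86), followed by Cyp26b1, which degrades retinoic acid, at 48.2% (46.1% ± 2.81). The segmentation factors Gbx2, Mafb and Egr2 were covered to 41.3%, 31.4% and 23.0%, and Rarb was lowest at 14.4%. Over 10 genes of the midbrain-hindbrain boundary the median was 31.6% against 16.8% (percentile 99.9), with Lmx1b at 65.4%, Fgf17 at 46.7%, En2 at 33.4% and Pax8 lowest at 12.3%.

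Dorsoventral progenitor genes, signalling genes and early neuronal genes were also above the random lists. The 24 dorsoventral genes had a median of 21.2% against 12.2% (percentile 99.9), and all 24 exceeded the median of all genes. Pax7 and Pax3, paired box factors of dorsal progenitors, were covered to 68.6% (66.9% ± 4.75) and 51.9% (51.2% ± 4.91). Atoh1, the proneural gene of the rhombic lip, had 8.73%, and Nkx2-9 was lowest at 7.41%. The 22 signalling genes had a median of 26.8% against 15.1% (percentile 100 after rounding), led by Lfng, a modifier of NOTCH receptors, at 56.8% and Ptch1, the SHH receptor, at 56.8%. Dhrs3 was lowest at 8.01%. The 23 genes of newly born neurons had a median of 20.8% against 11.3% (percentile 99.9). Gata3 and Elavl3 were highest at 33.2% and 32.3%, Phox2b, a factor of branchial and visceral motor neurons, had 11.8%, and the X-linked Dcx had none in replicated peaks. With windows of 100 kb this list fell within the random lists (percentile 96.7).

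**Figure D2:**
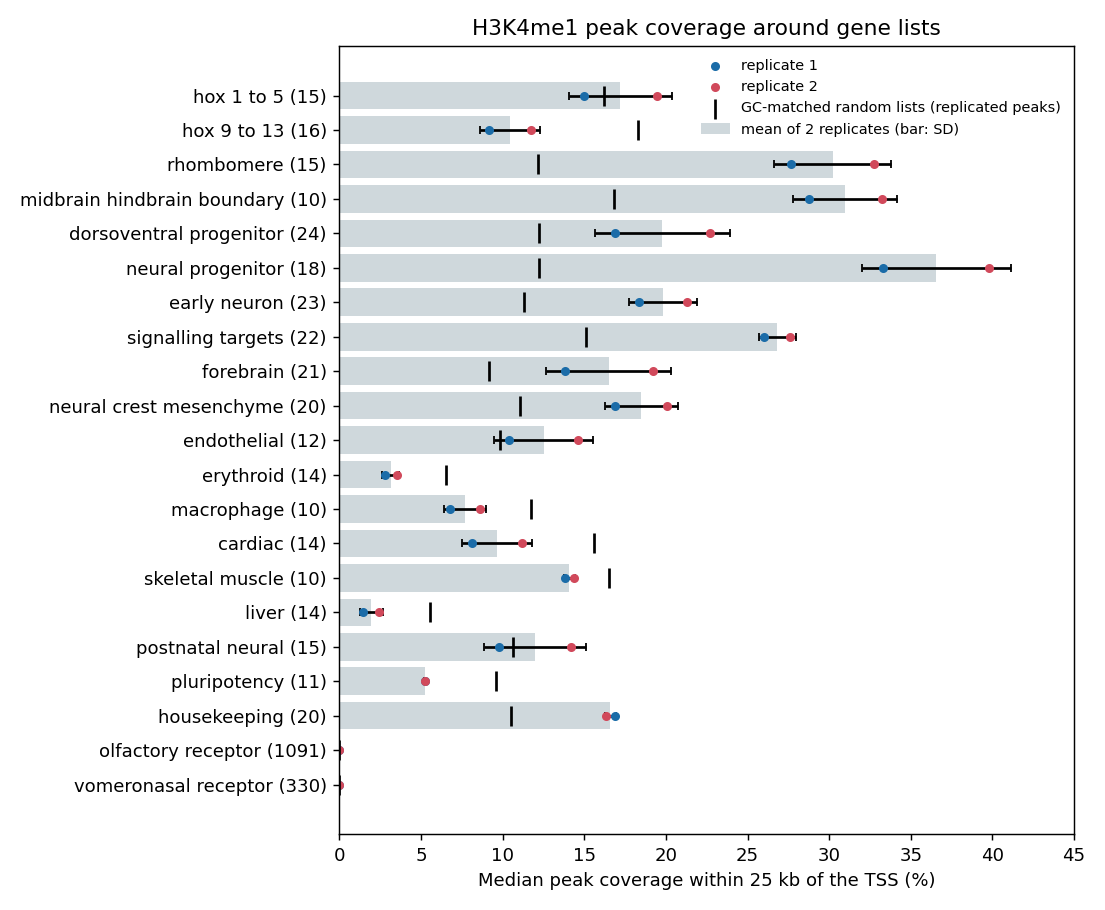
Median percent of the 25 kb on either side of the TSS covered by H3K4me1 peaks (x axis) for each gene list (y axis, number of genes in brackets). Grey bars are the mean of the 2 replicates with the SD, dots are the replicates, and black ticks are the median of GC-matched random lists for the replicated peaks; the neural progenitor genes stand highest, at 36.6% ± 4.59 over the replicates.

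Lists of other regions and cell types divided into those above, within and below the random lists. Forebrain genes had a median of 17.7% against 9.16% (percentile 99.9). Among them Dlx1 had 37.2%, the eye field gene Six3 19.5%, the telencephalic factor Foxg1 10.2%, and the X-linked Arx was lowest at 6.28%. Neural crest and mesenchyme genes, from cells that lie beside the hindbrain, had a median of 19.5% against 11.1% (percentile 99.4). Prrx2 had 49.5% and Sox10, a factor of migrating crest and glia, 47.5% (44.2% ± 3.05), whereas Snai2 had 2.90%. Endothelial genes lay within the random lists at 12.5% (percentile 81.9), with Egfl7 at 41.4%, Kdr at 6.98% and Erg at 3.19%. Erythroid genes had 3.34% (percentile 4.77), with Slc4a1 at 20.7% and none at Alas2 or the embryonic globin gene Hbb-bh1. With windows of 10 kb this list lay below the random lists (percentile 0.62). In the other 9 of 10 alternative settings it lay within them, up to percentile 46.8 with the 2.5 kb around the TSS left out. Macrophage genes had 7.75% (percentile 9.45), with Cd68 at 28.1% and none at Ptprc.

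Of the heart, skeletal muscle and liver lists, heart and liver lay below the GC-matched random lists, but neither did once promoter class was matched too. Liver genes had a median of 2.12% against 5.56% (percentile 1.94): Apoa1 was highest at 10.9%, Alb, which encodes serum albumin, had 1.26%, and Cps1 had none. Cardiac genes had 9.13% against 15.6% (percentile 1.42), with Myl7 at 37.8%, the atrial myosin gene Myh6 at 4.90% and Tbx5 lowest at 4.46%. This call ended in 6 of 10 alternative settings, as with windows of 10 kb (percentile 20.6), and the liver call ended in 3 of 10: with windows of 100 kb (percentile 6.14), with random lists matched also on CpG-rich promoters (percentile 29.9, random median 2.97%) and with the 2.5 kb around the TSS left out (percentile 27.8). Most of the liver deficit was thus gone once promoter class was matched. The cardiac list then lay within the random lists as well (percentile 3.1, random median 14.7%). Skeletal muscle genes lay within the random lists at 13.5% (percentile 23.3), from Tnnt3 at 45.4% to Myf5 at 5.97%. Over the 143 genes of the hindbrain lists, which also hold the Hox genes of groups 9 to 13, the median was 20.9% ± 3.16, and over the 38 genes of heart, skeletal muscle and liver it was 7.74% ± 1.38 (SD, n = 2). The difference was 13.1 ± 1.78 percentage points, 11.9 in replicate 1 and 14.4 in replicate 2. This difference is not matched on sequence: 67.8% of the hindbrain-list genes and 10.5% of the others have a CpG-rich TSS. Among genes without a CpG-rich TSS it was 10.3 ± 1.83 points, and with the median of genes of the same GC decile and promoter class taken off each gene it was 8.06 ± 1.55. After that step the hindbrain-list genes had a median of 7.51 ± 1.76 points and the others -0.549 ± 0.210. The matched difference thus came mostly from high coverage of the hindbrain-list genes. The unmatched difference grew to 20.6 points with windows of 10 kb and shrank to 4.96 points with windows of 100 kb.

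The remaining lists served as references. Housekeeping genes had a median of 17.8% against 10.5% (percentile 99.2), from Rplp0 at 40.3% to the X-linked Hprt at 1.85%, and all 20 had a peak within 1 kb of the TSS. In replicate 2 alone this list fell within the random lists (percentile 96.1). Genes of mature neurons and glia had 11.3% (percentile 56.9), with Camk2a at 60.5% and Gabra6 at 1.56%. Pluripotency genes had 5.09% (percentile 3), with Pou5f1 at 18.9% and none at Dppa4, and lay below the random lists in replicate 2 alone (percentile 2.27). In the other 9 of 10 alternative settings they lay within them, up to percentile 40.4 with windows of 10 kb. Of 1091 olfactory receptor genes 88.0% had no coverage, and of 330 vomeronasal receptor genes 94.8% had none. The highest of them were Olfr221 at 15.9% and Vmn1r4 at 4.19%. Both families and their GC-matched random lists had a median of 0 and so were tied (percentiles 50 and 48.8). With windows of 100 kb, and against unmatched lists, both families had a percentile of 0.

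Hox genes, which give the hindbrain its positional identity, differed between clusters. The 15 genes of paralogue groups 1 to 5, those used in the hindbrain, had a median of 16.8% (percentile 56.8), with Hoxa1 at 23.3%, Hoxa2 at 20.8%, Hoxb1 at 17.6% and Hoxc4 lowest at 3.47%. The 16 genes of groups 9 to 13, used in the trunk and limbs, had a median of 10.4% against 18.3% in random lists (percentile 0.34), with Hoxd11 at 19.8%, Hoxd10 at 18.8% and Hoxb13 lowest at 3.54%. Without GC matching the groups 1 to 5 were above the random lists (percentile 98.5) and the groups 9 to 13 within them (percentile 81.0). The call of groups 9 to 13 also ended with windows of 100 kb (10.9% against 12.3%, percentile 19.6). With the 2.5 kb around the TSS left out it ended on the limit itself (9.67% against 15.6%, percentile 2.5). The early minus late difference was 6.75 ± 1.33 percentage points (SD, n = 2), and both replicates gave the same sign. By cluster it was 7.63 ± 1.68 in HoxA and 11.0 ± 2.96 in HoxB, but -1.26 ± 0.718 in HoxC and -1.35 ± 0.264 in HoxD. Windows of neighbouring Hox genes share most of their sequence, so these genes are not independent values. The whole HoxC cluster (chromosome 15, 102921103 to 103036852) was covered to 6.00% ± 1.96, compared with 19.4% ± 3.30 for HoxA (chromosome 6, 52155590 to 52260880), 11.2% ± 1.75 for HoxB (chromosome 11, 96194316 to 96368256) and 19.2% ± 2.71 for HoxD (chromosome 2, 74668310 to 74765142).

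**Figure D3:**
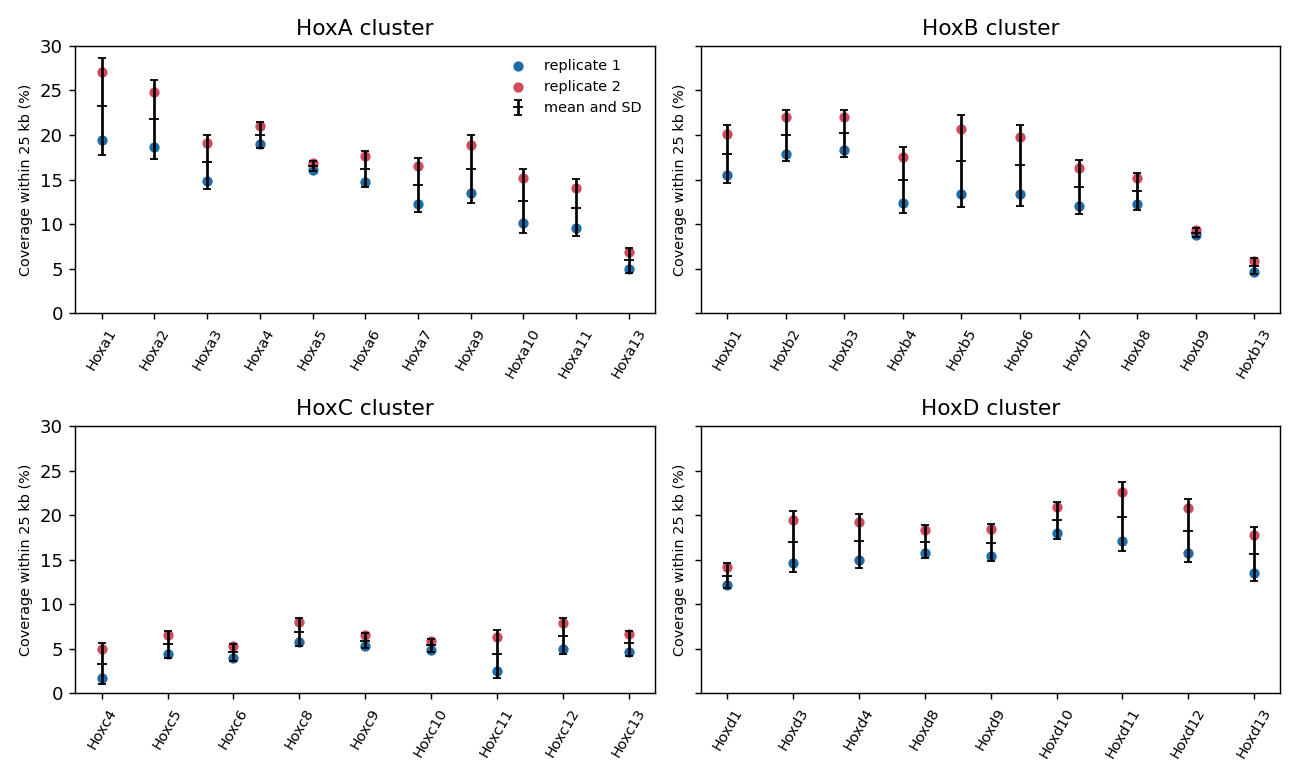
Percent of the 25 kb on either side of the TSS covered by H3K4me1 peaks (y axis) for the Hox genes of each cluster in paralogue order (x axis). Dots are the 2 replicates and black marks their mean with the SD; in HoxA and HoxB the coverage is lowest at group 13 (Hoxb13 5.26% ± 0.918), in HoxC it is low throughout, and in HoxD it does not fall towards the late groups.

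Of the 16 genes fixed in advance, 15 had a replicated peak within 25 kb, and the midpoint of the strongest lay over 1 kb from the principal TSS in 12 and closer in 3 (Atoh1, Foxg1 and Kdr). Since 1 kb is a small part of the 25 kb searched on each side, peaks placed at random would also mostly lie farther away. Within 25 kb of the Egr2 TSS there were 9 replicated peaks. The strongest (chromosome 10, 67534989 to 67537118) had a fold enrichment of 7.27 and a midpoint at -1.815 kb from the principal TSS, in an annotated intron of Egr2. It spans the annotated start of the gene (67535475), upstream of the principal TSS, so it may not be distal. Near Mafb there were 14 replicated peaks, the strongest intergenic, 18.2 kb downstream of the TSS (chromosome 2, 160347524 to 160350137, fold enrichment 7.61). Near En2 there were 18, the strongest intergenic, 14.4 kb downstream of the TSS (chromosome 5, 28179384 to 28180745, fold enrichment 4.85). Near Sox2 there were 15, the strongest 18.5 kb downstream of the TSS (chromosome 3, 34665495 to 34672232, fold enrichment 7.19). Sox10 had 20, the strongest over an exon of the gene itself (chromosome 15, 79155018 to 79157681, fold enrichment 9.03). The highest fold enrichments of the 16 genes were those of Sox10, Gbx2 (8.05), Mafb, Egr2 and Sox2, followed by the cardiac gene Myh6 at 6.23, and the endothelial gene Kdr had 5.17. The peak counted for Myh6 lay at -7.556 kb from its TSS, within the neighbouring gene Myh7. Alb had 1 peak, in an intron, with a fold enrichment of 3.55, and Hbb-bh1 had none.

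Joined across gaps of up to 1 kb, the replicated peaks formed 102768 domains, the longest of which lay in gene bodies. The longest, 97.2 kb, held the TSS of Gse1 (chromosome 8, 120481192 to 120578407), of which 96.2% ± 0.538 was covered in the replicates (SD, n = 2). The long gene model Gm20388 overlaps the same region and had 25.5% at its own TSS, and a further Gse1 domain of 62.5 kb ranked in the top 10. The next lay in Casz1 (80.3 kb), over Ccdc85c and only the end of Ccnk (77.0 kb), in Ssbp3 (74.6 kb), in Zmiz1 (68.3 kb) and in Msi2, an RNA-binding protein of neural progenitors (63.5 kb and 44.9 kb). Sept9 (47.0 kb) and the ephrin receptor Ephb2 (44.9 kb) completed the top 10. Gse1 remained the longest at 97.154 kb in replicate 2 and 97.210 kb in replicate 1 alone. The rest of the top 10 was less stable: 7 of the 10 overlapped the top 10 of replicate 2 alone and of peaks with a q-value under 1e-05, 9 that of replicate 1 alone, and 6 that of peaks joined across 3 kb. Domains of at least 10 kb numbered 1192 and held the TSS of 2.56% of all genes. They held the TSS of 9 of 18 neural progenitor genes (among them Notch1, Sox2, Hes1 and Hes5), 5 of 10 boundary genes (En2, Fgf17, Lmx1b, Pax2 and Wnt1), 6 of 22 signalling genes, 8 of 24 dorsoventral genes and 4 of 15 rhombomere genes. Among the early neuron genes they held 1 of 23, close to the share of all genes, and among the Hox genes of groups 1 to 5 and 9 to 13 none, where the share of all genes gives fewer than 1.

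Distal replicated peaks, over 2.5 kb from any TSS, were compared with unmarked windows of equal GC content for 13 short motifs. All 13 were more frequent in peaks. The ratio was highest for the core of the CTCF motif, an insulator protein, at 2.02 (1.91 ± 0.180 over the replicates, SD, n = 2), which 1.43% of peak windows held. It was 1.72 for MEF2 (1.65 ± 0.0177), 1.47 for the paired NFI motif (1.38 ± 0.153) and 1.43 for the homeodomain motif TAATTA (1.38 ± 0.00141), which 23.3% of peak windows held against 16.3% of background windows. TEAD had 1.36, ETS 1.34, POU 1.25, RFX 1.23, the E-box CAGCTG of proneural factors 1.21, PBX-HOX 1.16 and SOX 1.12. The motifs of HNF4, a liver factor, and of GATA factors had the lowest ratios, at 1.08 (1.08 ± 0.0206) and 1.06 (1.06 ± 0.00694). Peaks shifted along the chromosomes gave mean ratios from 0.994 for POU to 1.11 for ETS and 1.13 for CTCF. HNF4, at 1.06 with a q-value under 1e-05, 1.06 in replicate 1 and 1.07 over 10 kb from a TSS, lay within the range of its shifted peaks (highest 1.07) in 3 of 5 alternative settings. With windows of 400 bp MEF2 was highest at 1.97 and CTCF had 1.67, and in replicate 2 NFI had 1.27, below TAATTA, ETS and TEAD.

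**Figure D4:**
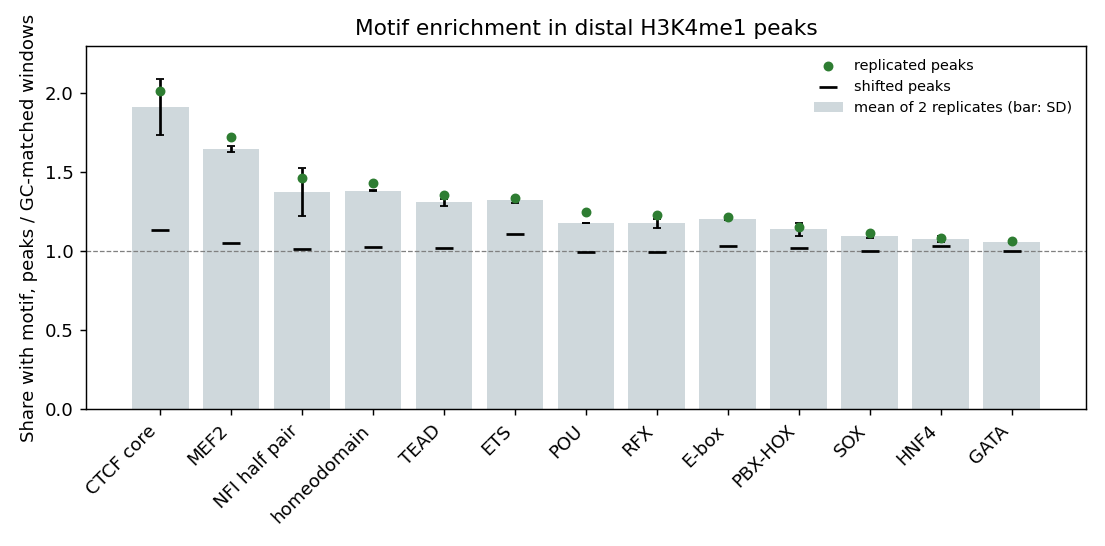
Share of distal peak windows with a motif divided by its share in GC-matched windows outside peaks (y axis) for 13 motifs (x axis). Bars are the mean of the 2 replicates with the SD, green dots the replicated peaks and black ticks the shifted peaks; CTCF (1.91 ± 0.180) and MEF2 (1.65 ± 0.0177) have the highest bars.

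Few peaks were called on chromosome X. Peaks covered 0.496% of it in replicate 1 and 0.727% in replicate 2, compared with autosome means of 6.15% and 6.85%. The ratio of X to autosomes was 0.0934 ± 0.0180 (SD, n = 2). This is a ratio of called peak length, and for the share of CpG-rich TSSs with a peak within 1 kb the ratio was 0.586 ± 0.106. The gene-rich chromosome 11 had the highest coverage, 10.7% ± 0.759, and chromosome 3 the lowest of the autosomes, 4.40% ± 0.394. Several lowest members of the gene lists were X-linked (Sox3, Dcx, Arx, Hprt and Alas2), and leaving out X-linked genes changed the call of no list. It did raise the erythroid median from 3.34% to 5.57% (percentile 28.25) and the pluripotency median from 5.09% to 8.02% (percentile 13.3).

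**Figure D5:**
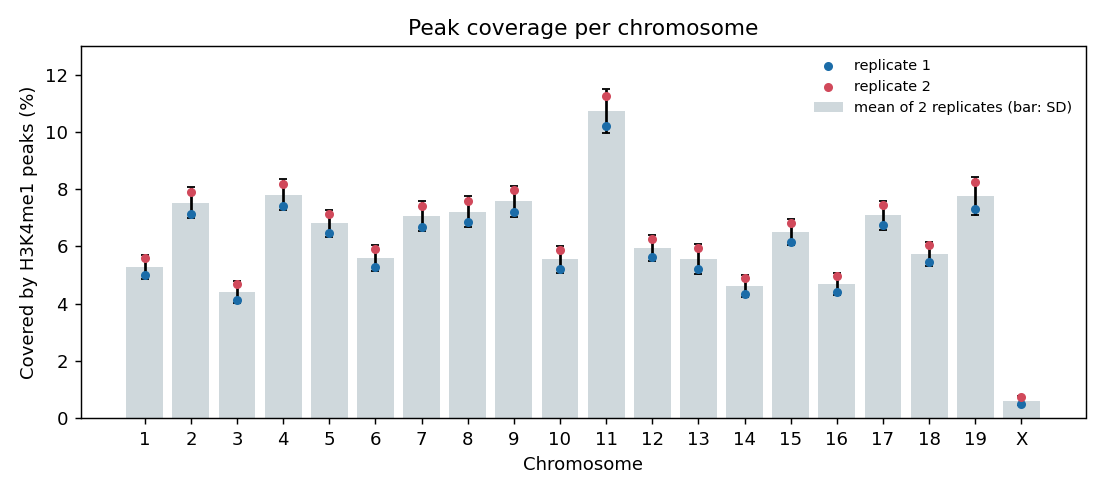
Percent of each chromosome covered by H3K4me1 peaks (y axis) against chromosome (x axis). Bars are the mean of the 2 replicates with the SD and dots the replicates; chromosome X lies at 0.611% ± 0.163, below every autosome in both replicates.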

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

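Depth is unknown, so it cannot be said how far the weak peaks depend on it. The Hox clusters taken alone, X-linked genes left out, lists matched on CpG-rich promoters, the hindbrain minus other tissue difference by promoter class, windows without the TSS and X at CpG-rich TSSs were added after the data were seen. The count of motifs with a ratio over 1 replaced a count at 1.2 after the ratios were seen, because POU and RFX lay under 1.2 in each replicate alone (1.18 for POU in both). Unless a construction shows it, the cause was not tested. No paired analysis was possible because there is 1 group.

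With peaks of a q-value under 1e-05 only, the mean peak number fell to 96866.5 per replicate and the covered length to 112 Mb, Spearman's rho was 0.674, the replicated share 94.6%, the hindbrain minus other tissue difference 10.7 percentage points, the longest domain 86.6 kb and the X to autosome ratio 0.0692. With peaks within 1 kb joined there were 124120 per replicate over 190 Mb, and with 3 kb the longest domain was 331 kb. Rho was 0.797 for fold times width and 0.763 for reciprocal overlap of 50%. The 50% overlap rule computed here kept 52.9% of pooled peaks. CpG-rich TSSs alone gave a flank to centre ratio of 1.32. With windows of 10 kb the early minus late Hox difference was 8.62 points over the replicates and the hindbrain minus other tissue difference 20.6, and with 100 kb the latter was 4.96. That difference was 10.3 points among genes without a CpG-rich TSS and 8.06 with the median of the same GC decile and promoter class taken off. The Hox difference was 11.0 points in HoxB alone and reversed in HoxC (-1.26) and HoxD (-1.35). In the replicated list the early and late Hox medians were 16.8% and 10.4% with windows of 25 kb. They lay closer with 10 kb (13.5% and 9.95%) and with 100 kb (12.9% and 10.9%), so the growth at 10 kb was not seen in that list. Among CpG-rich TSSs the X to autosome ratio of the share with a peak was 0.586.

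Leaving out a replicate gave 206700 to 240660 peaks, 147 to 164 Mb, a longest domain of 97.154 to 97.210 kb, a Hox difference of 5.81 to 7.70 points and an X ratio of 0.0807 to 0.106. The overlap of replicates (64.5% to 77.5% over 3 alternatives) and the promoter share (9.11% to 16.5% over 5) stayed above the shifted lists. All 13 motif ratios stayed above 1 over 5, but 1 is not the level of shifted peaks, and HNF4 lay within the range of its shifted peaks (highest 1.07) in 3 of the 5. The number of called gene lists was 10 to 13 over 10 alternatives. The rhombomere, boundary, dorsoventral, neural progenitor, signalling, forebrain and neural crest lists kept their call in all 10, early neuron and housekeeping in 9, Hox 9 to 13 and liver in 7, and cardiac in 4.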

Other observations

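Gene families chosen by symbol also differed, but many share members with the gene lists above (among them Sox2, Zic1, Pax7, Irx3, Lhx2, Epha4, Notch1 and Fgf17) and partly repeat their values. The 20 families were chosen after the results above were known and before their own values were. Against GC-matched random lists, 12 lay above, 4 below and 4 within the central 95%. Zic genes, zinc finger factors of the dorsal neural tube, had a median coverage of 43.0% against 8.66% (39.2% ± 8.997 over the replicates, SD, n = 2), with Zic5 at 54.7% and the X-linked Zic3 at 6.95%. Ephrins had 44.7% against 20.1% (43.9% ± 3.73), NOTCH receptors and ligands 37.5% against 20.0%, Iroquois genes 31.0% against 13.4%, paired box genes 29.8% against 11.2%, ephrin receptors 23.3% against 10.3%, semaphorins 24.1% against 11.9% and SOX genes 23.8% against 10.4%. The 67 replication histone genes, which lie in clusters and share windows, had 24.0% against 5.36%. WNT ligands (28.4%, percentile 95.1), fibroblast growth factors (12.6%, percentile 90.8) and bone morphogenetic proteins (6.59%, percentile 26.9) lay within the random lists. Keratins had 7.28% against 14.4%, and the clustered protocadherins and beta defensins had medians of 0. Family members that lie side by side share windows and are not independent values. The random lists draw genes from the whole genome, so the percentiles of such families are not calibrated. Of 51 clustered protocadherin genes 45 had no coverage, yet Pcdhgc5, at the end of the gamma cluster and outside the symbols counted, had 73.8% (71.3% ± 5.23).

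Genome-wide, after Gse1 (91.7%), the genes with the highest coverage were Zfhx3, a homeobox gene (86.3%, 84.3% ± 2.60), Sept9 (85.7%), Fignl2 (81.1%), Cirbp (81.0%), 1600002K03Rik (78.1%), the co-repressor Tle3 (77.8%), Nuak2 (76.9%), Notch1 (76.3%) and Bahcc1 (76.0%). Cirbp and 1600002K03Rik are neighbours on chromosome 10 (TSSs at 80167778 and 80172944). Their windows share most of their sequence, so they are not independent values. On chromosome X, 54.6% of 948 genes had no coverage, against 17.4% of autosomal genes. Bcor, a transcriptional co-repressor, was the highest X-linked gene at 52.8% (51.1% ± 3.79), rank 238 of all genes, followed by Efnb1 at 33.1%, Pja1 at 30.1% and Rtl5 at 21.01%.

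The 3 tests on chromosome X below were chosen after their results had been seen. Gene windows on X were covered to 0.275 of autosomal windows of the same GC deciles in replicate 1 and to 0.330 in replicate 2, and GC matching itself lowered the autosomal mean from 11.1% to 4.82% in replicate 1, so low GC content goes with part of the gap and not the whole. Among CpG-rich TSSs, at most 64.2% on X had a peak within 1 kb, below the lowest autosome (90.1% and 90.6%), which argues against a lack of CpG-rich promoters as the whole cause. A lower X signal put through a fixed peak limit remained. The factor that makes autosomal CpG-rich promoters match those on X was 0.521 to 0.567 over 3 fold limits and both replicates, a range of 0.0461. It was fitted at each limit, so the match is by construction and only the small range is a result. It covers CpG-rich promoters alone and not the low covered length of X. The lower signal at these promoters may reflect the X dose of mixed-sex pools or silencing of an X in female cells. These were not separated because the labels give no sex ratio. Mappability and the control were not tested, and no biological explanation was tested by the design.

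Replicate 2 covered 14.3 percentage points more of CpG-rich TSS centres than replicate 1. With the strongest peaks of each up to the same covered length, 11.2 points (78.7%) remained, which argues against more called length alone as the cause. It does not test depth, since a deeper library also gives wider peaks and dropping weak peaks does not undo this. A bias of replicate 2 towards GC-rich sequence is also argued against. Away from TSSs the most GC-rich decile of bins had 0.969 of the overall replicate 2 to replicate 1 ratio. At 60% to 70% GC the ratio was 1.11 away from TSSs and 1.45 at the centres. The replicates did differ with GC in the other direction: away from TSSs the ratio fell from 1.53 in the lowest GC decile to 1.08 in the highest. Replicate 2 filled 40.4% of the sequence of short replicate 1 gaps over CpG-rich TSSs and 32.5% of those over 10 kb from a TSS, a difference of -7.97 points, while replicate 1 filled 11.0% and 20.99% of replicate 2 gaps at these places, which left open whether replicate 2 fills gaps everywhere. A difference in depth, in fragment length, in antibody yield or in the dissected tissue may remain and could not be tested with peak lists. No biological explanation was tested.

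Forebrain genes lay above the random lists although the tissue was hindbrain. CpG-rich promoters are argued against, since the percentile was 99.8 with lists matched also on promoter class. Peaks at the principal promoters of these genes alone are argued against as well, since it was 99.8 with 2.5 kb on either side of the principal TSS left out. Other TSSs of these genes and promoters of neighbouring genes stayed in the windows. Promoter peaks in general were therefore not tested. Over all 10 alternatives the percentile of the forebrain list stayed between 97.6 and 100 after rounding. The housekeeping reference list also lay above the random lists (17.8% against 10.5%, percentile 99.2), close to the forebrain list (17.7% against 9.16%). Lying above them was thus not particular to genes of a brain region. Marking of developmental genes beyond the region that expresses them and forebrain tissue in the dissection may both be candidate explanations, and neither was tested because no other tissue was measured.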
